A study of Homo sapiens with 12 samples.

How the data were processed

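MyLa cells, an established CTCL cell line, were grown in medium with 20 ng/mL interleukin-2 and treated for 24 h with DMSO, 3.2 nM romidepsin, 5.7 uM afatinib dimaleate or both, with the DMSO volume matched to that of the combination, per the labels' protocols. Total RNA was taken with a column kit, and libraries were prepared and sequenced by a service company, per the labels' protocols. The kit of the libraries, the selection of RNA and the strand are not given in the sources used here. The deposited table holds whole-number counts of read pairs per gene name for 59050 names and 12 libraries, made with featureCounts 2.0.0 and GENCODE 31 from paired reads, with a check of the fragment length, without chimeric pairs, with both ends mapped, without a strand option and without multi-mapping reads, per the file headers. Reads were aligned with STAR 2.7.9a to GRCh38.p12, and DESeq2 1.38.1 was named too, per the submitters' processing notes. The values are whole numbers without scaling. Reads shared by near-identical genes are left out by this counting, and reads of overlapping or antisense genes are not separated by strand, so the values of such genes are uncertain.

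A second deposited table, named as normalized counts, was checked against the counts and not used in any comparison. Of its 13315 genes, 13 names had turned into dates and 13302 could be compared. In each of the 12 libraries every count had exactly 1 code in this table, and the codes followed the order of the counts sorted as text (Spearman correlation 1.0) and not their size (0.022 to 0.049), so the values are not normalized counts.

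Libraries were grouped by the treatment in their labels, 3 per group. Total counts per library were 8972228 to 12696653, and the level of 3 counts was 0.236 to 0.334 CPM. Genes were kept by edgeR's filterByExpr with the groups, which left 16208 genes, and scaled by TMM factors. CPM values use these factors. The main test was edgeR 4.0.16 in R 4.3.3, with glmQLFit (robust) and glmQLFTest on 4 group means over all 12 libraries, so that every comparison shared one estimate of the spread (biological coefficient of variation 6.13%), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The 6 contrasts were each drug and the combination against DMSO, the combination against each drug, and the interaction, which is the log2 change of the combination minus the sum of the log2 changes of both drugs. Counts of genes changed at least 2-fold use the same test with an absolute log2 fold change of at least 1.

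The tests, the alternatives, 42 gene lists and the rule for named genes were chosen before the data were examined. Lists covered the drug targets, cytokine and kinase signalling, cell cycle and DNA repair, cell death, stress responses, metabolism, T cell identity and function, and markers of other cell types. The 39 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with the correlation estimated from the data. Camera compares a list with the other genes. Named genes were, from each comparison with DMSO, up to 8 genes higher and 8 lower, from the combination against each drug up to 5 and 5, and from the interaction up to 6 and 6, namely those with the largest absolute log2 fold change among genes past the threshold with a mean of at least 5 CPM over the 12 libraries and a gene symbol that is not a clone name. Pairwise comparisons also required that all 3 libraries of a group lay above all 3 of the other. Each list added up to 4 members per comparison with the largest absolute log2 fold change among those past the threshold with at least 5 CPM, or else its most abundant member. The ERBB receptors, HDAC1, HDAC2, HDAC3, CDKN1A, MYC, JAK1, JAK3, STAT3, STAT5A, STAT5B and ABCB1 were always included. Some genes that meet the rule are not reported here. Coordinates come from the count table. Gene types and olfactory receptors were taken by name from GENCODE 29, which matched 56378 of the 59050 names (95.5%).

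Each test was also run on simulated data. Counts were drawn for the tested genes from the means, dispersions and library sizes of these libraries. In each comparison 200 genes with an average of at least 10 counts were changed by known folds, 50 at each of 4 sizes, and edgeR ran on 15564 to 15579 genes. In the simulated comparison of romidepsin with DMSO, 74% of the genes changed 1.5-fold were recovered, 88% of those changed 2-fold and 98% of those changed 4-fold, with 8 calls among unchanged genes. The corresponding values were 68%, 84% and 96% with 9 such calls for afatinib, and 70%, 88% and 100% with 4 for the combination. They were 80%, 82% and 98% with 9 for the combination against romidepsin, and 76%, 80% and 98% with 7 for the combination against afatinib. The interaction gave 60%, 60% and 88% with 8. Camera called a list of 20 genes moved together 1.5-fold in all 6 simulated comparisons and 0 of the other 38 lists at the adjusted threshold. The genes were drawn independently of each other and the other lists were random. These values therefore do not test false list calls that come from correlated genes.

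The alternatives were RLE size factors, upper-quartile factors and library size only, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, only the compared groups in the fit, the replicate number as a block, a minimum fold, an estimated correlation for the lists, and leaving out each library in turn. Leaving out the 4 libraries with more than 10 counts of KRT5 and KRT14 together, and leaving out DMSO replicate 3 with romidepsin replicate 2, were added after seeing the data. List tests were repeated with RLE size factors, the block, the CPM filter, the estimated correlation and left-out libraries. For the overlap of the single-drug responses, counts were simulated 20 times from the fitted means and dispersions, with the changes of afatinib shuffled among genes within 20 classes of DMSO abundance and shared simulated DMSO libraries, which was added after seeing the data. Other splits of the libraries were counted for each comparison, with all 10 splits of 6 libraries for the pairwise ones. For the interaction, 100 splits of the 12 libraries were drawn with a fixed seed. For the overlap of the single-drug responses, 100 splits were drawn that shuffled only the libraries outside the combination. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.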

Results

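Gene expression was measured by bulk RNA sequencing in MyLa cells, an established cell line from cutaneous T cell lymphoma (CTCL). The cells were kept for 24 h with DMSO, with 3.2 nM romidepsin, with 5.7 uM afatinib dimaleate, or with both drugs, and each of the 4 groups had 3 libraries. Romidepsin inhibits histone deacetylases, and afatinib inhibits the kinases of the ERBB receptor family. All cells grew with interleukin-2 at 20 ng/mL, and every condition held the same volume of DMSO. The series was designed around the synergy of the drugs, so the comparisons address what each drug changed alone, what the combination changed, and where the combination differed from the sum of the single-drug changes. Libraries held from 8972228 counts (romidepsin replicate 2) to 12696653 counts (combination replicate 2). A gene without a count in a library was therefore limited to 0.236 to 0.334 CPM (normalised read counts per library), the level of 3 counts, which covers counting error only.

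At least 1 count was found for 22430 ± 562 genes in DMSO, 23076 ± 375 in afatinib, 23669 ± 728 in romidepsin and 24528 ± 273 in the combination (mean ± SD, n = 3 libraries). Mitochondrially encoded transcripts took 12.9% ± 1.69 of the counts in DMSO, 10.9% ± 0.165 in afatinib, 12.8% ± 0.956 in romidepsin and 11.9% ± 0.804 in the combination, with the highest share, 14.8%, in DMSO replicate 3. The first principal component of the 16208 tested genes took 63.2% of the variance and set the romidepsin and combination libraries apart from the other two groups, and the second took 17.3%. Reads of keratinocyte keratins stood in 4 libraries. KRT5 had 126 counts in afatinib replicate 3, 94 in DMSO replicate 2, 59 in DMSO replicate 1 and 43 in combination replicate 1, and at most 1 in each of the other 8 libraries. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which can be technical. CPM values below are means ± SD over the 3 libraries of a group, coordinates are on GRCh38, and the counts of list members are adjusted over all tested genes, with the count adjusted over the list alone where it differed.

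**Figure D1:**
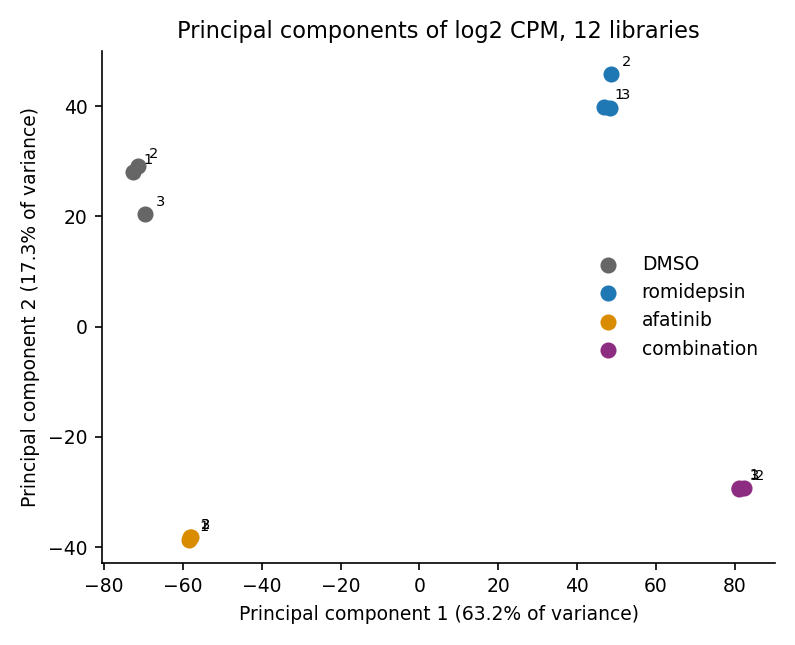
Scores of the 12 libraries on the first 2 principal components of log2 CPM, with the share of variance on each axis (63.2% and 17.3%) and 1 point per library coloured by group. The 3 libraries of each group lie together, and romidepsin and the combination lie on the positive side of the first component. On the second component DMSO replicate 3 scored 20.4, against 28.0 and 29.1 for DMSO replicates 1 and 2. Romidepsin replicate 2 scored 45.8 there, against 39.9 and 39.7 for romidepsin replicates 1 and 3.

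Romidepsin alone changed 62.6% of the tested genes, with 5039 higher and 5100 lower than in DMSO (edgeR, adjusted p below 0.05), of which 2157 and 1763 moved at least 2-fold. It raised STC1 from near the detection limit and IL22 from a low level. Immediate early genes and neuronal genes rose, and genes of DNA replication, mitosis and the T cell receptor complex fell. STC1, which encodes the glycoprotein hormone stanniocalcin 1 (chromosome 8, 23841929 to 23854806), rose from 0.405 ± 0.281 to 91.7 ± 10.1 CPM (log2 fold change 7.83, SE 0.18, edgeR adjusted p = 1.78e-36). The cytokine gene IL22 (chromosome 12, 68248242 to 68253604) rose from 1.84 ± 1.22 to 202 ± 1.599 CPM (log2 fold change 6.80, SE 0.14, edgeR adjusted p = 6.07e-34). FAM43A rose by a log2 fold change of 5.29 and HPCAL4 by 5.02. HLF, a transcription factor gene (chromosome 17, 55264960 to 55325187), rose from 2.65 ± 0.708 to 99.6 ± 8.36 CPM (log2 fold change 5.24, SE 0.14, edgeR adjusted p = 8.59e-34). On the other side, the chemokine gene CCL22 (chromosome 16, 57358783 to 57366189) fell from 46.8 ± 4.17 to 1.65 ± 0.513 CPM (log2 fold change -4.79, SE 0.18, edgeR adjusted p = 5.27e-28). The homeobox gene MKX fell from 10.7 ± 0.374 to 0.262 ± 0.128 CPM. ADTRP and RBPJL had log2 fold changes of -4.42 and -3.71. Values of SMIM10L2B (6.16), RGPD1 (-3.68), RGPD3 (-4.26), RGPD4 (-4.00) and KCNJ18 (-3.71) are uncertain, since these genes share reads with near-identical copies.

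Of 39 gene lists with at least 5 tested members, 13 moved with romidepsin by camera, 7 up and 6 down, and 8 of these also passed with an estimated correlation between genes. Among the genes often raised by histone deacetylase inhibitors, 14 of 18 tested members rose, 1 fell and 3 were not called, and adjusted over the list alone 15 rose and 1 fell (median log2 fold change 1.89, camera adjusted p = 6.76e-07). CRIP2 rose by 4.37 on the log2 scale, the histone gene HIST2H2BE by 3.92 and TXNIP, whose product inhibits thioredoxin, by 3.19. CDKN1A, which encodes the cell cycle inhibitor p21, went from 297 ± 21.2 to 1283 ± 41.3 CPM (log2 fold change 2.11, SE 0.06, edgeR adjusted p = 3.55e-34). In the list of MAPK feedback and immediate early genes, 16 of 24 tested members rose, 1 fell and 7 were not called (median log2 fold change 0.77, camera adjusted p = 3.1e-05). The transcription factor genes EGR2 (3.97) and FOS (3.01) rose most, followed by PHLDA1 (2.87) and DUSP2 (2.42). Neuronal genes under the repressor REST rose as a list (9 of 12 tested members rose, 1 fell and 2 were not called, camera adjusted p = 0.00485). Their leading member SYN1, the gene of the synaptic vesicle protein synapsin 1, had a log2 fold change of 3.73, followed by the granule protein gene CHGB (2.18) and SYP (2.09). Genes of endoplasmic reticulum chaperones and of the unfolded protein response moved by less. There 13 of 19 tested members rose, 2 fell and 4 were not called (median log2 fold change 0.35, camera adjusted p = 0.00485), and CRELD2 came first (1.16).

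Cell cycle lists fell with romidepsin. In S phase, 3 of 38 tested members rose, 33 fell and 2 were not called (median log2 fold change -0.82, camera adjusted p = 5.57e-09), among them the replicative helicase gene MCM5 (-1.76, SE 0.08), E2F8 (-1.57) and UHRF1 (-1.56). In G2 and M phase, 2 of 45 tested members rose, 37 fell and 6 were not called (median log2 fold change -0.74, camera adjusted p = 3.1e-09). UBE2C fell by a log2 fold change of -1.66, GTSE1 by -1.52 and FOXM1, a transcription factor of mitotic genes, by -1.37. Homologous recombination and Fanconi genes fell as well (3 of 28 tested members rose, 18 fell and 7 were not called, camera adjusted p = 0.00271). FANCD2 had a log2 fold change of -1.40 and BRCA1 of -1.10. In the T cell receptor list, 3 of 18 tested members rose, 11 fell and 4 were not called (median log2 fold change -0.93, camera adjusted p = 0.00281). Other members were too rare to be tested, among them CD3E with at most 4 counts in any library, and LCK and CD4 with at most 1. CD2 fell by a log2 fold change of -1.88, the kinase gene ZAP70 by -1.81 and CD247, which encodes the zeta chain of the receptor complex, by -1.76. The other 5 calls were lost with an estimated correlation. Cholesterol synthesis genes (16 of 25 tested members rose, 5 fell and 4 were not called, camera adjusted p = 0.000723) had adjusted p = 0.0804 with an estimated correlation. HMGCS1 rose most (2.51). Lysosome and autophagy genes (18 of 27 tested members rose, 3 fell and 6 were not called, camera adjusted p = 0.000229) had adjusted p = 0.0852 with an estimated correlation, led by GABARAPL1 (5.02) and NEU1 (3.50). Hypoxia response genes (9 of 15 tested members rose, 3 fell and 3 were not called, camera adjusted p = 0.0481) had adjusted p = 0.117 with an estimated correlation, with NDRG1 at 4.29. This call was also lost with a filter of at least 1 CPM in 3 libraries (adjusted p = 0.0507). MYC targets in ribosome biogenesis (3 of 30 tested members rose, 22 fell and 5 were not called, camera adjusted p = 0.000148) had adjusted p = 0.144 with an estimated correlation. MHC class I genes (2 of 15 tested members rose, 8 fell and 5 were not called, camera adjusted p = 0.0306) had adjusted p = 0.457 with an estimated correlation and 0.0558 without DMSO replicate 2.

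Afatinib alone changed 45.4% of the tested genes, with 3571 higher and 3780 lower than in DMSO (edgeR, adjusted p below 0.05), of which 1031 and 412 moved at least 2-fold. Among the gene lists its highest medians were those of the amino acid stress response (1.58), interferon-stimulated genes (1.31) and NRF2 targets of oxidant defence (0.81), while mitotic, ribosome biogenesis and T cell cytokine genes fell. CHAC1, which encodes an enzyme that degrades glutathione (chromosome 15, 40952962 to 40956512), rose from 3.55 ± 1.04 to 84.6 ± 5.49 CPM (log2 fold change 4.60, SE 0.11, edgeR adjusted p = 1.33e-34). INHBE, the gene of an inhibin subunit (chromosome 12, 57452323 to 57459280), rose by a log2 fold change of 4.79, SE 0.26, and ANGPT4, the gene of an angiopoietin, by 4.62, SE 0.28. KLHDC7B (chromosome 22, 50546203 to 50551023) went from 7.18 ± 1.001 to 131 ± 3.26 CPM (log2 fold change 4.18, SE 0.10, edgeR adjusted p = 2.03e-34). BEST1, HYAL4 and the mucin gene MUC5B rose by 4.04, 3.99 and 3.92. CCL22 fell to 2.95 ± 0.704 CPM (log2 fold change -3.97, SE 0.16, edgeR adjusted p = 8.67e-26). The immediate early gene EGR1 (chromosome 5, 138465479 to 138469303) fell from 21.8 ± 3.47 to 3.05 ± 0.956 CPM (log2 fold change -2.84, SE 0.19, edgeR adjusted p = 1.03e-16). The list of MAPK feedback and immediate early genes, which holds EGR1, did not pass as a list with afatinib (camera adjusted p = 0.688). Its members moved both ways, and SPRY4 (3.12), SPRED1 (1.55) and ETV5 (1.53) rose. GSDME, which encodes a pore-forming gasdermin, fell from a mean of 18.5 to 2.75 CPM. RGS9 had a log2 fold change of -2.83, ZBTB10 of -2.15 and GBP1, which encodes a guanylate-binding protein, of -2.12. The value of HNRNPA1P21 (-2.08), a pseudogene that shares reads with its parent, is uncertain.

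Of the 39 lists, 20 moved with afatinib by camera, 6 up and 14 down, and 11 of these also passed with an estimated correlation. In the list of ATF4 targets, which answer a shortage of amino acids, 24 of 25 tested members rose and 1 was not called (median log2 fold change 1.58, camera adjusted p = 1.69e-34). SESN2 rose by a log2 fold change of 3.62, DDIT3, which encodes the stress factor CHOP, from 5.47 ± 0.84 to 48.5 ± 2.39 CPM (log2 fold change 3.15, SE 0.12, edgeR adjusted p = 1.36e-27), and the pseudokinase gene TRIB3 by 3.00. NRF2 targets, genes of oxidant defence, rose as a list (12 of 15 tested members rose, 1 fell and 2 were not called, camera adjusted p = 6.46e-11). OSGIN1 rose by a log2 fold change of 3.72, the cystine transporter gene SLC7A11 by 2.47 and NQO1 by 1.99. Lysosome and autophagy genes rose (23 of 27 tested members rose, 1 fell and 3 were not called, camera adjusted p = 3.05e-12), with the autophagy receptor gene SQSTM1 at 2.56. Cholesterol synthesis genes rose too (17 of 25 tested members rose, 1 fell and 7 were not called, and adjusted over the list alone 17 rose and 2 fell, camera adjusted p = 2.07e-08), with MVK at 1.22. Among interferon-stimulated genes, 14 of 23 tested members rose, 6 fell and 3 were not called, and adjusted over the list alone 16 rose and 6 fell (median log2 fold change 1.31, camera adjusted p = 0.000265). IFIT2 went from 19.5 ± 2.198 to 137 ± 3.76 CPM (log2 fold change 2.82, SE 0.09, edgeR adjusted p = 4.68e-30). OASL rose by 1.86 and the transcription factor gene IRF7 by 1.76.

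Downward, 36 of 45 tested members fell and 9 were not called in the list of G2 and M phase genes (median log2 fold change -0.54, camera adjusted p = 1.86e-14), with CCNB1, the gene of cyclin B1, at -1.07 and BUB1 at -0.95. In ribosome biogenesis, 29 of 30 tested members fell and 1 was not called (median log2 fold change -0.50, camera adjusted p = 9.09e-15), with GNL3 at -1.01 and the nucleolin gene NCL at -0.92. T cell cytokines and chemokines fell as a list (2 of 16 tested members rose, 10 fell and 4 were not called, camera adjusted p = 2.33e-05). IL9 fell by a log2 fold change of -1.99, LTB by -1.75 and the lymphotoxin gene LTA by -1.72. STAT3 and STAT5 targets fell (3 of 20 tested members rose, 14 fell and 3 were not called, camera adjusted p = 3.03e-06), including the kinase gene PIM2 at -1.25 and JUNB at -1.08. Nuclear-encoded subunits of the respiratory chain fell too (18 of 31 tested members fell and 13 were not called, camera adjusted p = 2.24e-05), with UQCRFS1 at -0.62. Genes reported as raised or lost in CTCL cells fell (3 of 16 tested members rose, 11 fell and 2 were not called, camera adjusted p = 0.00495). TOX fell by -0.69 and BCL11B by -0.69, and both encode T lineage transcription factors. The other 9 calls were lost with an estimated correlation. Glycolysis genes (2 of 22 tested members rose, 13 fell and 7 were not called, camera adjusted p = 0.0011) had adjusted p = 0.159 with an estimated correlation, with LDHA at -1.04. The 13 mitochondrially encoded messenger RNAs, of which 9 fell (camera adjusted p = 0.000245), had adjusted p = 0.42 with an estimated correlation. The mitochondrial share of counts was also lowest in this group. NF-kB targets (3 of 20 tested members rose, 11 fell and 6 were not called, camera adjusted p = 0.002) had adjusted p = 0.055 with an estimated correlation. T lineage transcription factors (1 of 23 tested members rose, 12 fell and 10 were not called, and adjusted over the list alone 2 rose and 12 fell, camera adjusted p = 0.0123) had adjusted p = 0.0844 with an estimated correlation.

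Of the remaining 5 afatinib calls, 4 also ended without the libraries holding keratin reads. S phase genes (5 of 38 tested members rose, 20 fell and 13 were not called, and adjusted over the list alone 5 rose and 21 fell, camera adjusted p = 0.0115) had adjusted p = 0.164 with an estimated correlation and 0.202 without those libraries. Heat shock chaperones (2 of 15 tested members rose, 11 fell and 2 were not called, camera adjusted p = 0.00349) had adjusted p = 0.244 with an estimated correlation and 0.123 without those libraries. MHC class I genes (8 of 15 tested members fell and 7 were not called, camera adjusted p = 0.00895) had adjusted p = 0.264 with an estimated correlation. MHC class II genes (1 of 8 tested members rose, 5 fell and 2 were not called, camera adjusted p = 0.0355) had adjusted p = 0.338 with it. Both lists had adjusted p = 0.432 without those libraries. The class II call was also lost without afatinib replicate 3 (adjusted p = 0.0723) and without DMSO replicate 2 (adjusted p = 0.0673). Genes often raised by histone deacetylase inhibitors (4 of 18 tested members rose, 1 fell and 13 were not called, camera adjusted p = 0.0407) had adjusted p = 0.178 with an estimated correlation. They lost the call without any 1 of 7 libraries, namely afatinib replicate 2 or 3, DMSO replicate 1 or 3, combination replicate 1 or romidepsin replicate 1 or 2 (adjusted p = 0.0501 to 0.0712). Leaving out the 4 libraries with keratin reads, an alternative chosen after seeing the data that keeps a single DMSO library, lowered the afatinib calls to 2164 higher and 1998 lower. With library size as the only scaling, 62.2% of the afatinib calls were higher, against 48.6% with TMM factors, and the median of all genes shifted by 0.10 on the log2 scale.

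The responses to the single drugs overlapped. Of the genes tested in both comparisons with DMSO, 1574 were higher with each drug and 1988 lower, 3562 in the same direction, and 1730 went in opposite directions. Independent lists of the same sizes would share 1110.2 higher and 1189.4 lower genes. Independent changes were simulated 20 times with the same design, an addition made after seeing the data. Romidepsin kept its fitted changes, those of afatinib were shuffled among genes of similar abundance, and both were compared with the same simulated DMSO libraries. These simulations gave 3060 to 3254 genes in the same direction and 2344 to 2525 in opposite directions, so the real count of 3562 lay above their highest. They called more genes than the real data (10564 to 10670 for romidepsin and 7907 to 8139 for afatinib), so their counts in opposite directions are not like for like with the real 1730. The log2 fold changes of all genes had the same sign in 59.5% of the genes (52.9% to 54.5% simulated), a correlation of 0.255 (0.18 to 0.236 simulated) and a covariance of 0.212 that lay within the simulated 0.165 to 0.225. Genes are not independent replicates. Without the libraries holding keratin reads, 1982 genes changed in the same direction.

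The combination changed 74.3% of the tested genes, with 6026 higher and 6010 lower than in DMSO (edgeR, adjusted p below 0.05), of which 3424 and 2974 moved at least 2-fold. STC1 and IL22, which romidepsin had raised, were high, CHAC1 rose above its level with afatinib alone, and most genes of DNA replication, mitosis and the T cell receptor complex were lower than in DMSO. STC1 stood at 96.4 ± 4.03 CPM (log2 fold change 7.91, SE 0.18, edgeR adjusted p = 2.63e-37), and IL22 at 90.3 ± 5.299 CPM (log2 fold change 5.64, SE 0.15, edgeR adjusted p = 1.15e-30). CHAC1 reached 432 ± 30.0 CPM (log2 fold change 6.95, SE 0.10, edgeR adjusted p = 2.38e-44). RGMA, which encodes a repulsive guidance molecule (chromosome 15, 93035273 to 93089204), rose by a log2 fold change of 5.99, SE 0.29, the calpain gene CAPN5 by 5.73, SE 0.21 and TMEM86A by 5.69, SE 0.25. DACT3, a gene of a Wnt signalling modulator (chromosome 19, 46647551 to 46661182), went from 1.47 ± 0.14 to 70.1 ± 1.84 CPM (log2 fold change 5.57, SE 0.14, edgeR adjusted p = 3.27e-35). GPR183, which encodes the receptor of oxysterols on lymphocytes (chromosome 13, 99294539 to 99307399), fell from 30.5 ± 2.55 to 0.826 ± 0.43 CPM (log2 fold change -5.18, SE 0.21, edgeR adjusted p = 4.56e-27). CSF2RB, the gene of the shared beta chain of the receptors for IL-3, IL-5 and GM-CSF (chromosome 22, 36913628 to 36940439), fell from 175 ± 7.12 to 6.61 ± 1.397 CPM (log2 fold change -4.72, SE 0.10, edgeR adjusted p = 4.78e-39). MKX (-5.27), the transcription factor genes TFAP2C (-4.93) and ZBTB10 (-4.73), HTR3B (-4.63) and CCL22 (-4.61) were lower as well. The median of all genes shifted by 0.123 with upper-quartile factors and by 0.104 with library size only, so smaller log2 changes than these depend on the scaling.

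**Figure D2:**
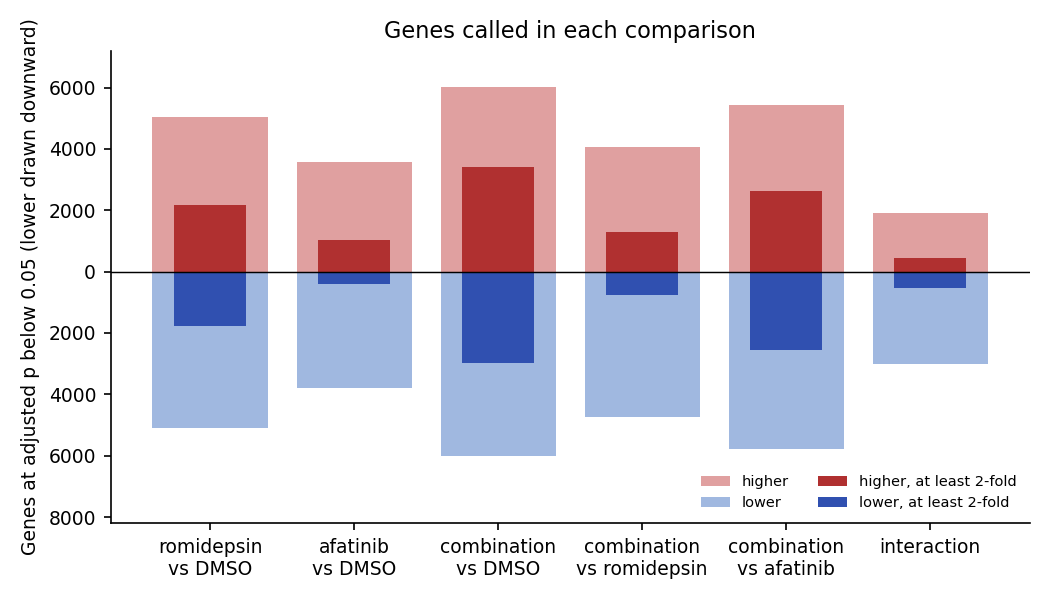
Number of genes past the threshold (edgeR, adjusted p below 0.05), higher and lower, in each of the 6 comparisons, with the part that changed at least 2-fold drawn darker. The combination against DMSO has the most (6026 higher and 6010 lower) and the interaction the fewest (1895 and 3003).

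Of the 39 lists, 16 moved in the combination by camera, 9 up and 7 down, and 9 of these also passed with an estimated correlation. In G2 and M phase, 1 of 45 tested members rose, 43 fell and 1 was not called (median log2 fold change -1.36, camera adjusted p = 1.05e-12). MKI67, the gene of the proliferation marker Ki-67, went from 1507 ± 126 to 271 ± 1.84 CPM (log2 fold change -2.48, SE 0.06, edgeR adjusted p = 2.16e-36). PLK1, the gene of a mitotic kinase, had a log2 fold change of -2.31, SE 0.07. In S phase, 4 of 38 tested members rose and 34 fell (median log2 fold change -1.21, camera adjusted p = 1e-09), with E2F8 at -2.71 and the helicase genes MCM7 and MCM5 at -2.57 and -2.56. For homologous recombination and Fanconi genes, 2 of 28 tested members rose, 22 fell and 4 were not called (camera adjusted p = 9.14e-05), with FANCD2 at -2.61 and the checkpoint kinase gene CHEK1 at -1.60. In the T cell receptor list, 2 of 18 tested members rose, 13 fell and 3 were not called (median log2 fold change -1.21, camera adjusted p = 0.00109), among them CD2 (-2.86), UBASH3A (-2.64) and CD3G (-2.57). Genes often raised by histone deacetylase inhibitors stayed raised (14 of 18 tested members rose, 3 fell and 1 was not called, camera adjusted p = 8.49e-05), with CRIP2 at 4.83 and GADD45B at 3.52. NRF2 targets rose (11 of 15 tested members rose, 3 fell and 1 was not called, camera adjusted p = 0.000248), with SRXN1 at 3.48. Cholesterol genes rose too (20 of 25 tested members rose, 3 fell and 2 were not called, camera adjusted p = 1.7e-06). INSIG1, which encodes a sterol-regulated brake on that pathway (chromosome 7, 155297776 to 155310235), went from 82.6 ± 0.785 to 1434 ± 51.0 CPM (log2 fold change 4.12, SE 0.06, edgeR adjusted p = 1.42e-44). Lysosome and autophagy genes rose (21 of 27 tested members rose, 3 fell and 3 were not called, camera adjusted p = 1.52e-06), with the sialidase gene NEU1 at 5.20, SE 0.13 and MAP1LC3B at 3.95, SE 0.07. MAPK feedback and immediate early genes rose (16 of 24 tested members rose, 3 fell and 5 were not called, camera adjusted p = 0.00106), with the feedback inhibitor gene SPRY4 at 4.04 and ETV5 at 3.98.

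The other 7 list calls of the combination were lost with an estimated correlation. ATF4 targets (18 of 25 tested members rose, 4 fell and 3 were not called, camera adjusted p = 2.61e-05) had adjusted p = 0.057 with an estimated correlation. DDIT3 still rose by a log2 fold change of 4.10, SE 0.11 and the asparagine synthetase gene ASNS by 3.30, SE 0.17. Neuronal genes under REST (9 of 12 tested members rose, 2 fell and 1 was not called, camera adjusted p = 0.0106) had adjusted p = 0.0552 with an estimated correlation, with SYN1 at 3.79. Endoplasmic reticulum chaperone and unfolded protein response genes (10 of 19 tested members rose, 5 fell and 4 were not called, camera adjusted p = 0.0251) had adjusted p = 0.0634 with an estimated correlation, with HERPUD1 at 3.03. Fatty acid synthesis genes (6 of 9 tested members rose, 2 fell and 1 was not called, camera adjusted p = 0.0391) had adjusted p = 0.157 with an estimated correlation, with FASN, the fatty acid synthase gene, at 2.32. Costimulatory and inhibitory receptors (4 of 16 tested members rose, 11 fell and 1 was not called, camera adjusted p = 0.00854) had adjusted p = 0.057 with an estimated correlation. TIGIT had a log2 fold change of -3.16 and CD40LG of -2.94. MYC targets in ribosome biogenesis (2 of 30 tested members rose, 25 fell and 3 were not called, camera adjusted p = 5.14e-07) had adjusted p = 0.0552 with an estimated correlation. MHC class I genes (3 of 15 tested members rose, 10 fell and 2 were not called, camera adjusted p = 0.0171) had adjusted p = 0.364 with an estimated correlation. In each list past the threshold of any comparison, the median, the mean and camera's direction had the same sign.

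**Figure D3:**
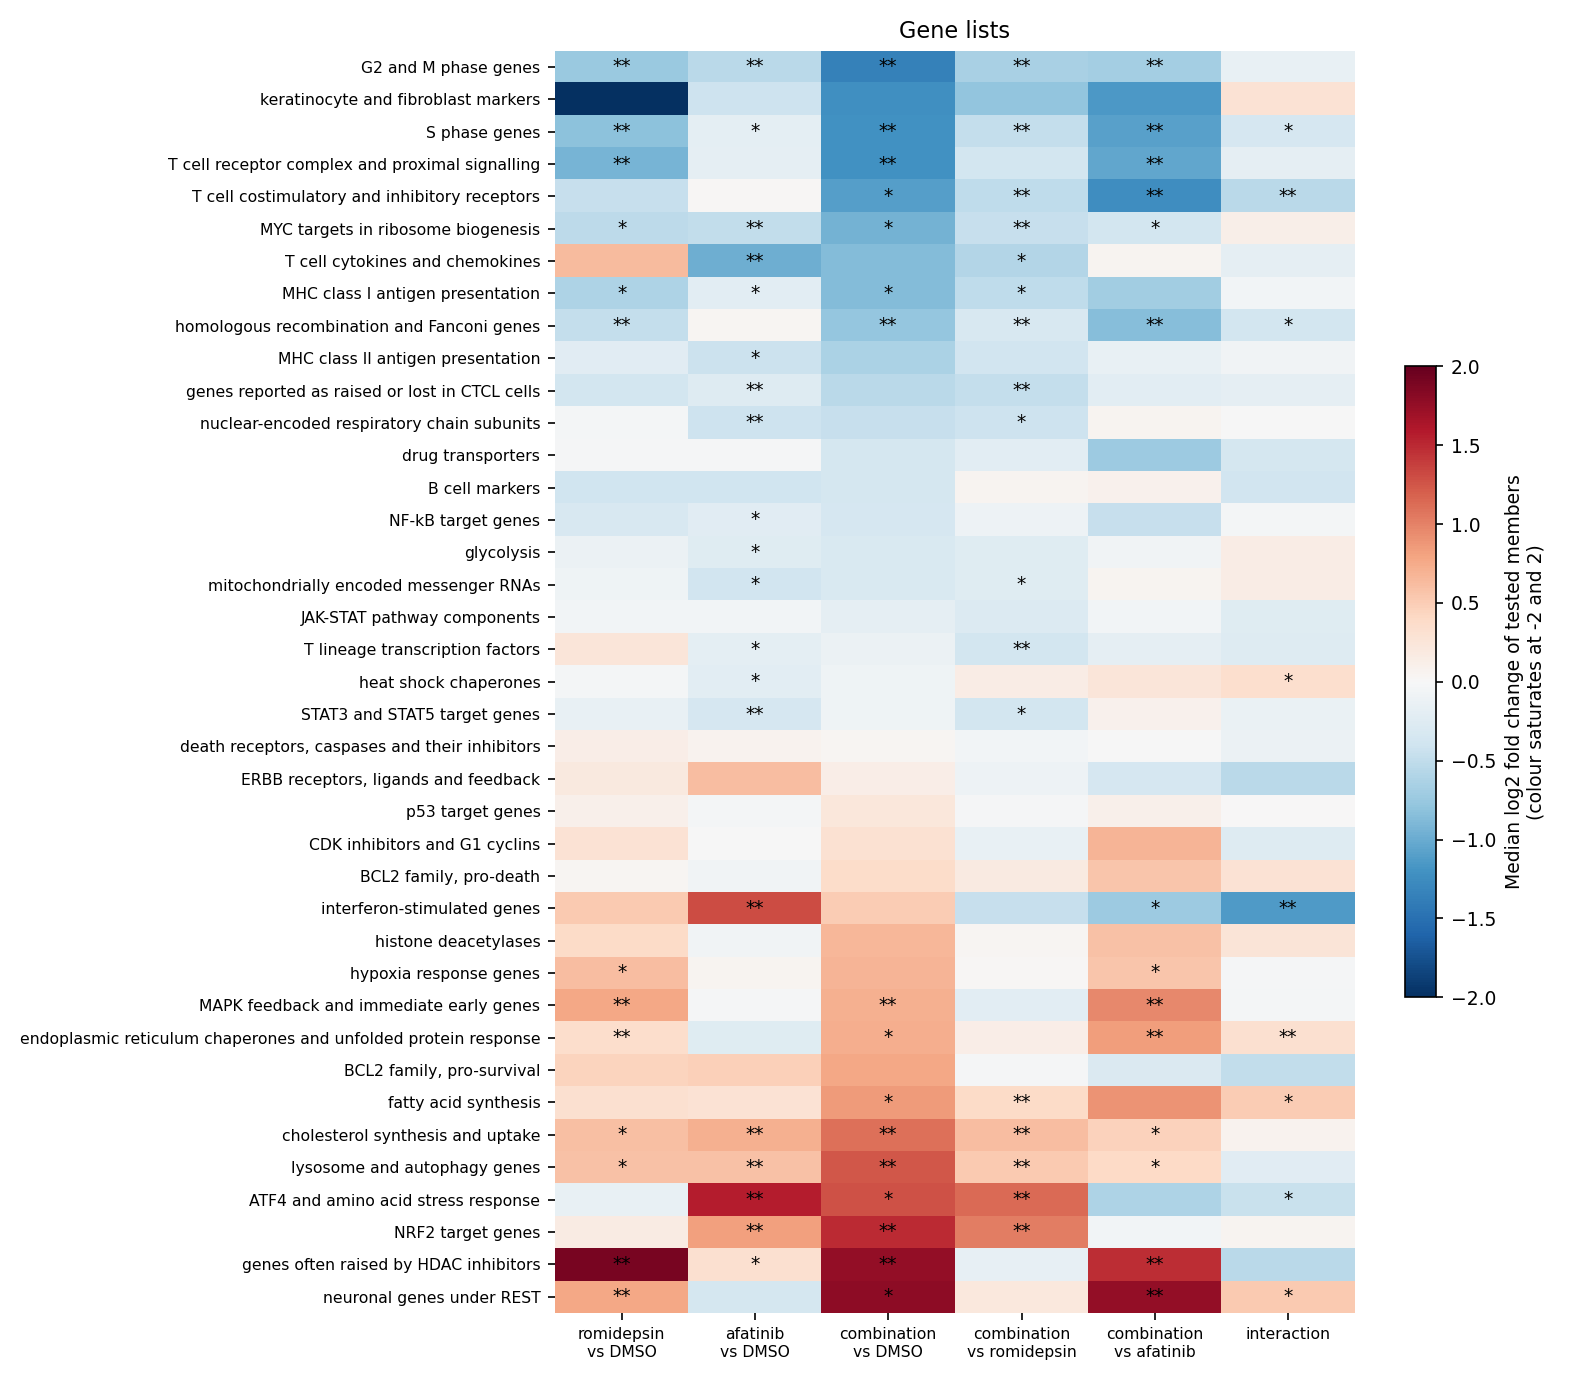
Median log2 fold change of the tested members of each of the 39 gene lists (one line per list) in the 6 comparisons (columns), as colour that saturates at -2 and 2, ordered by the combination against DMSO. A single star marks camera's call with the preset correlation and a double star one that also holds with an estimated correlation, such as G2 and M phase genes (-1.36) and NRF2 targets (1.49) in the combination.

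Against romidepsin alone, the combination showed what afatinib added to the histone deacetylase inhibitor, with 4069 genes higher and 4740 lower (edgeR, adjusted p below 0.05) and 1293 and 778 of these moved at least 2-fold. With upper-quartile factors 56.4% of these calls were higher, against 46.2% with TMM factors. The largest increases included 3 members of the list of ATF4 targets. CHAC1 rose from 9.22 ± 0.600 to 432 ± 30.0 CPM (log2 fold change 5.54, SE 0.09, edgeR adjusted p = 3.9e-42). DDIT3 (chromosome 12, 57516588 to 57521737) rose from 4.99 ± 0.743 to 93.2 ± 1.84 CPM (log2 fold change 4.24, SE 0.11, edgeR adjusted p = 2.23e-33), and ASNS by a log2 fold change of 3.36, SE 0.17. BEST1 rose by 4.03 and SPRY4 by 3.10. The cytokine genes LTA (-2.79), OSM (-2.64) and IL13 (-2.52) fell, as did APOL3 (-2.76). HLF, which romidepsin had raised, stood at 16.03 ± 1.73 CPM in the combination (log2 fold change -2.63, SE 0.10, edgeR adjusted p = 3.44e-26).

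Of the 39 lists, 17 moved in this comparison by camera, 5 up and 12 down, and 12 of these also passed with an estimated correlation. ATF4 targets rose (19 of 25 tested members rose, 3 fell and 3 were not called, and adjusted over the list alone 19 rose and 4 fell, camera adjusted p = 7.69e-14). NRF2 targets rose too (11 of 15 tested members rose, 2 fell and 2 were not called, camera adjusted p = 1.72e-07), with TXNRD1, the gene of a thioredoxin reductase, at 2.24. Genes of lipid synthesis rose on both branches. For cholesterol genes 21 of 25 tested members rose and 4 were not called (median log2 fold change 0.62, camera adjusted p = 3.94e-09), with INSIG1 at 1.92. For fatty acid synthesis 6 of 9 tested members rose and 3 were not called (median log2 fold change 0.39, camera adjusted p = 3.83e-05), with FASN at 1.93 and SCD at 1.15. Lysosome genes rose (19 of 27 tested members rose, 1 fell and 7 were not called, camera adjusted p = 4.62e-07). G2 and M phase genes fell further below their level with romidepsin (3 of 45 tested members rose, 38 fell and 4 were not called, and adjusted over the list alone 3 rose and 39 fell, camera adjusted p = 9.1e-12), with TTK at -1.22 and CCNA2 at -1.17. S phase genes did too (4 of 38 tested members rose, 24 fell and 10 were not called, and adjusted over the list alone 5 rose and 24 fell, camera adjusted p = 3.22e-06), with RRM1 at -1.22. Homologous recombination genes fell (1 of 28 tested members rose, 16 fell and 11 were not called, and adjusted over the list alone 1 rose and 19 fell, camera adjusted p = 0.00391), with BRCA2 at -0.93. Among T cell lists, costimulatory and inhibitory receptors fell (2 of 16 tested members rose, 11 fell and 3 were not called, and adjusted over the list alone 3 rose and 11 fell, camera adjusted p = 0.00195), with CD40LG at -1.57, although TNFRSF9 rose by 1.75. T lineage transcription factors fell (2 of 23 tested members rose, 14 fell and 7 were not called, camera adjusted p = 0.00258), with BACH2 at -1.87. Genes reported as raised or lost in CTCL cells fell (9 of 16 tested members fell and 7 were not called, camera adjusted p = 0.000645), with TNFRSF8, which encodes CD30, at -0.88. MYC targets in ribosome biogenesis fell (1 of 30 tested members rose, 25 fell and 4 were not called, and adjusted over the list alone 1 rose and 26 fell, camera adjusted p = 5.97e-08).

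The other 5 calls against romidepsin were lost with an estimated correlation. STAT3 and STAT5 targets (4 of 20 tested members rose, 11 fell and 5 were not called, and adjusted over the list alone 5 rose and 11 fell, camera adjusted p = 0.000645) had adjusted p = 0.0966 with an estimated correlation. T cell cytokines and chemokines (2 of 16 tested members rose, 9 fell and 5 were not called, camera adjusted p = 0.00325) had adjusted p = 0.0712 with an estimated correlation. Respiratory chain subunits (1 of 31 tested members rose, 18 fell and 12 were not called, camera adjusted p = 0.00312) had adjusted p = 0.0966 with an estimated correlation. MHC class I genes (2 of 15 tested members rose, 10 fell and 3 were not called, camera adjusted p = 0.0198) had adjusted p = 0.326 with an estimated correlation. Mitochondrially encoded messenger RNAs (1 of 13 tested members rose, 9 fell and 3 were not called, and adjusted over the list alone 2 rose and 10 fell, camera adjusted p = 0.0447) had adjusted p = 0.669 with an estimated correlation. This call was also lost with RLE size factors (adjusted p = 0.0615) and with a filter of at least 1 CPM in 3 libraries (adjusted p = 0.0529). It was lost too without any 1 of 5 libraries, namely afatinib replicate 1 or 3, combination replicate 1 or 3 or romidepsin replicate 3 (adjusted p = 0.0563 to 0.0999).

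Against afatinib alone, the combination showed what romidepsin added to the kinase inhibitor, with 5421 genes higher and 5798 lower (edgeR, adjusted p below 0.05) and 2638 and 2568 of these moved at least 2-fold. STC1 rose by a log2 fold change of 8.17, SE 0.18, IL22 by 6.75, SE 0.17, DACT3 by 6.73, SE 0.16 and the cytokine gene IL9 by 6.06, SE 0.10. KLHDC7B, which afatinib alone had raised, fell to 5.66 ± 0.852 CPM (log2 fold change -4.51, SE 0.11, edgeR adjusted p = 3.03e-36), and CSF2RB fell by a log2 fold change of -4.40, SE 0.10. Of the 39 lists, 14 moved by camera, 7 up and 7 down, and 9 of these also passed with an estimated correlation. Neuronal genes under REST rose (10 of 12 tested members rose and 2 were not called, and adjusted over the list alone 10 rose and 1 fell, camera adjusted p = 0.000276), with SYN1 at 5.68 and SCG2 at 3.56. Endoplasmic reticulum chaperone and unfolded protein response genes rose (14 of 19 tested members rose, 2 fell and 3 were not called, and adjusted over the list alone 14 rose and 4 fell, camera adjusted p = 0.000941), with CALR, the calreticulin gene, at 1.72. MAPK feedback genes (17 of 24 tested members rose, 3 fell and 4 were not called, camera adjusted p = 0.000301) rose too. So did the genes often raised by histone deacetylase inhibitors (13 of 18 tested members rose, 4 fell and 1 was not called, and adjusted over the list alone 14 rose and 4 fell, camera adjusted p = 0.000301). S phase genes fell (4 of 38 tested members rose, 33 fell and 1 was not called, camera adjusted p = 5.19e-09), with UHRF1 at -2.20. G2 and M phase genes fell (3 of 45 tested members rose, 38 fell and 4 were not called, and adjusted over the list alone 3 rose and 39 fell, camera adjusted p = 1.02e-07), with FOXM1 at -2.13. Homologous recombination genes (1 of 28 tested members rose, 23 fell and 4 were not called, camera adjusted p = 3.58e-05) fell. The T cell receptor list (2 of 18 tested members rose, 12 fell and 4 were not called, camera adjusted p = 0.00183) and costimulatory and inhibitory receptors (4 of 16 tested members rose and 12 fell, camera adjusted p = 0.000941) fell too, with TIGIT at -2.95.

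The other 5 calls against afatinib were lost with an estimated correlation. Interferon-stimulated genes (2 of 23 tested members rose, 13 fell and 8 were not called, camera adjusted p = 0.0237) had adjusted p = 0.0704 with an estimated correlation, with OAS2 at -2.37 and MX2 at -2.09. Cholesterol genes (15 of 25 tested members rose, 4 fell and 6 were not called, and adjusted over the list alone 16 rose and 4 fell, camera adjusted p = 0.00103) had adjusted p = 0.0788 with an estimated correlation. Lysosome genes (14 of 27 tested members rose, 7 fell and 6 were not called, and adjusted over the list alone 16 rose and 8 fell, camera adjusted p = 0.0165) had adjusted p = 0.264 with an estimated correlation. MYC targets in ribosome biogenesis (6 of 30 tested members rose, 17 fell and 7 were not called, camera adjusted p = 0.0339) had adjusted p = 0.424 with an estimated correlation. Hypoxia response genes (10 of 15 tested members rose, 3 fell and 2 were not called, camera adjusted p = 0.0424) had adjusted p = 0.104 with an estimated correlation and 0.0506 without combination replicate 3.

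**Figure D4:**
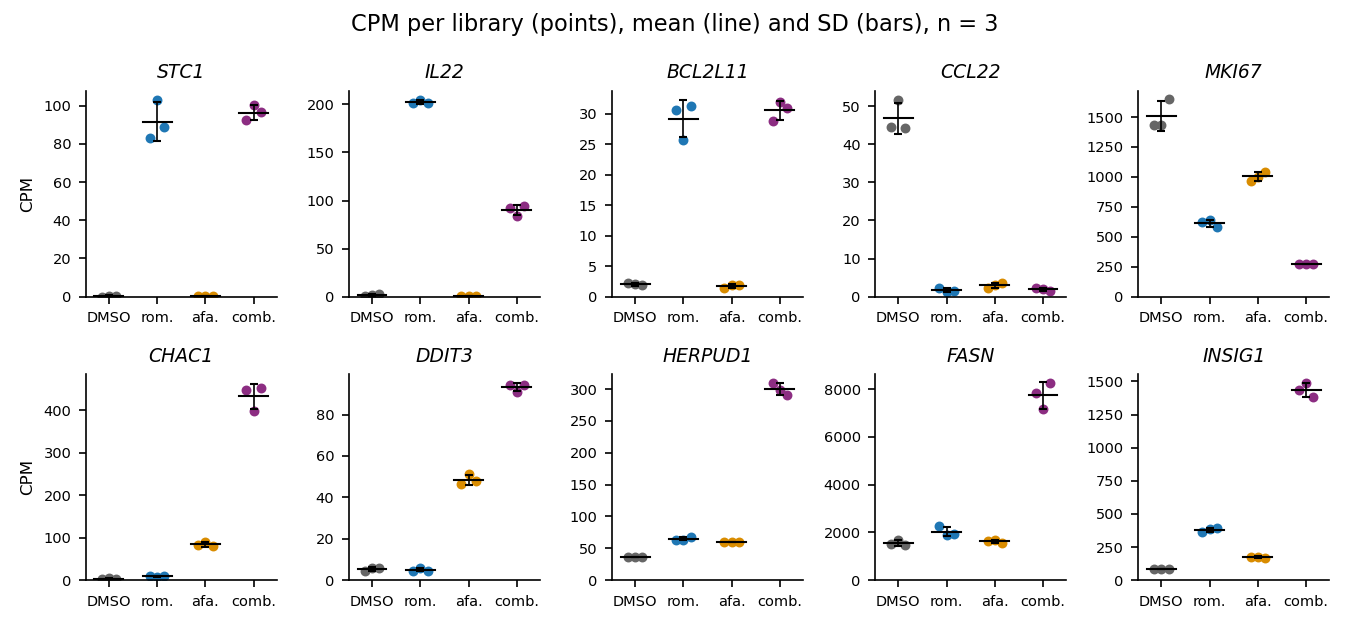
CPM on a linear scale of 10 named genes in the 12 libraries, 1 point per library with the group mean as a line and the SD as bars, in DMSO, romidepsin, afatinib and the combination. STC1 and IL22 rise with romidepsin with or without afatinib, CHAC1 goes from 3.55 CPM in DMSO to 432 in the combination, and HERPUD1 from 36.6 to 300.0.

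The interaction compared the combination with the sum of both single-drug log2 changes. It was higher than the sum for 1895 genes and lower for 3003 (edgeR, adjusted p below 0.05), 30.2% of the tested genes, with 450 and 534 at least 2-fold away. With upper-quartile factors 49.2% of these calls were higher, against 38.7% with TMM factors. Of the 4898 genes, 2291 lay further from DMSO than the sum (821 higher and 1470 lower), and 2607 fell short of it or went past zero. Among the 4898, 242 genes higher and 239 lower in the combination were called with neither drug alone, 85 and 44 of them at least 2-fold. The largest positive value was that of CCL22 (interaction 4.15, SE 0.34, edgeR adjusted p = 8.13e-14), which each drug alone had already brought below 3 CPM and which stood at 1.92 ± 0.419 CPM in the combination. SCG2, the secretogranin 2 gene (chromosome 2, 223596940 to 223602361), went from 19.4 ± 3.04 CPM in DMSO to 31.9 ± 2.09 with romidepsin, 7.74 ± 0.996 with afatinib and 91.1 ± 2.22 with both (interaction 2.85, SE 0.15, edgeR adjusted p = 6.38e-20). GSDME (2.81) and MEGF6 (2.69) lay below DMSO with each drug and with both, so their positive values mean a smaller fall than the sum. GSDME stood at 18.5 ± 0.237 CPM in DMSO and 1.87 ± 0.311 with both, and MEGF6 at 18.5 ± 1.71 and 8.84 ± 1.03. The glucose transporter gene SLC2A4 (2.57) stood at 6.545 ± 0.546 CPM in DMSO and 30.8 ± 1.28 with romidepsin. It was at 1.615 ± 0.362 CPM with afatinib and 45.5 ± 0.958 with both. HLF had the most negative value (interaction -3.88, SE 0.22, edgeR adjusted p = 8.02e-19), at 99.6 ± 8.36 CPM with romidepsin, 6.25 ± 1.33 with afatinib and 16.03 ± 1.73 with both. KLHDC7B (-2.89, SE 0.25), the transporter gene ABCA13 (-2.88, SE 0.23) and the corepressor gene TBL1X (-2.48, SE 0.29) were raised by afatinib and lay below the sum in the combination. Romidepsin given alone also raised ABCA13 (log2 fold change 1.12) and TBL1X (1.24), whereas KLHDC7B stood at 7.18 CPM in DMSO and 2.36 with romidepsin.

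Of the 39 lists, 9 moved in the interaction by camera, 4 up and 5 down, and 3 of these also passed with an estimated correlation. Interferon-stimulated genes lay below the sum as a list. There 1 of 23 tested members lay above the sum, 15 below it and 7 were not called. Adjusted over the list alone, 2 lay above and 18 below (median interaction -1.14, camera adjusted p = 6.19e-10). ISG15, the gene of a ubiquitin-like protein (chromosome 1, 1001138 to 1014540), stood at 23.8 ± 2.14 CPM in DMSO, 88.8 ± 2.15 with romidepsin, 56.4 ± 2.44 with afatinib and 31.04 ± 2.34 with both (interaction -2.77, SE 0.12, edgeR adjusted p = 1.44e-23). OASL went from 3.499 ± 0.745 CPM in DMSO to 16.4 ± 0.979, 12.6 ± 1.33 and 9.95 ± 0.922 in the same order (interaction -2.58, SE 0.23, edgeR adjusted p = 5.98e-13). IFIT2 went from 19.5 ± 2.198 to 27.8 ± 0.415, 137 ± 3.76 and 53.1 ± 7.03 (interaction -1.89, SE 0.13, edgeR adjusted p = 1.28e-16). RSAD2 had an interaction of -1.94, SE 0.21. Costimulatory and inhibitory receptors lay below the sum for 13 of 16 tested members and above it for 0, 14 and 0 adjusted over the list alone (median interaction -0.53, camera adjusted p = 1.08e-06). CD40LG had an interaction of -1.41, SE 0.14, CD276 of -1.01, SE 0.13 and ICOS of -0.69, SE 0.09. Endoplasmic reticulum chaperone and unfolded protein response genes lay above the sum for 11 of 19 tested members and below it for 3, 12 and 3 adjusted over the list alone (median interaction 0.31, camera adjusted p = 0.000301). HERPUD1 (chromosome 16, 56932142 to 56944864) was at 36.6 ± 0.259 CPM in DMSO, 64.7 ± 2.41 with romidepsin, 60.1 ± 0.466 with afatinib and 300.0 ± 9.71 with both (interaction edgeR adjusted p = 1.05e-17). MANF had an interaction of 0.98, SE 0.14. XBP1 went the other way, with 247 ± 5.11 CPM after afatinib and 68.7 ± 3.03 after both drugs (interaction -1.65, SE 0.09, edgeR adjusted p = 1.74e-19).

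**Figure D5:**
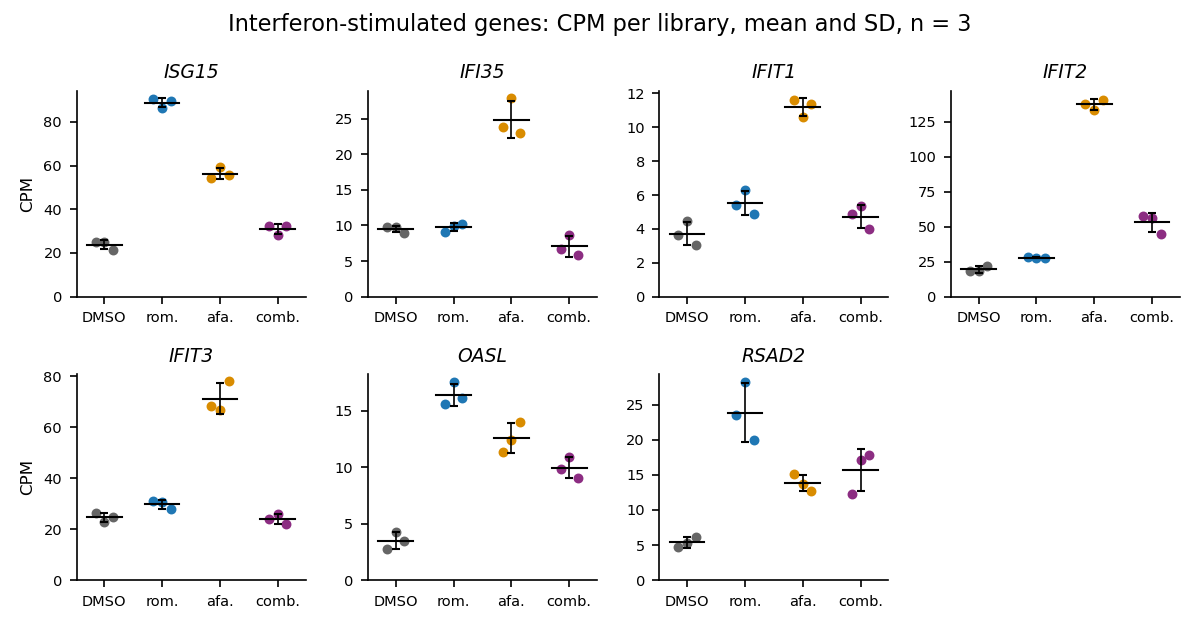
CPM on a linear scale of 7 interferon-stimulated genes in the 12 libraries, 1 point per library with the group mean as a line and the SD as bars, in DMSO, romidepsin, afatinib and the combination. ISG15 is at 88.8 CPM with romidepsin, 56.4 with afatinib and 31.04 with both drugs.

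The other 6 interaction calls were lost with an estimated correlation. Heat shock chaperones lay above the sum for 9 of 15 tested members and below it for 1 (camera adjusted p = 4.49e-05), with adjusted p = 0.182 with an estimated correlation and DNAJB1 at 1.16, SE 0.08. Fatty acid synthesis genes lay above it for 5 of 9 and below it for 0 (camera adjusted p = 0.000646), with adjusted p = 0.0555 with an estimated correlation. FASN (chromosome 17, 82078338 to 82098294) stood at 1556 ± 112 CPM in DMSO, 2036 ± 203 with romidepsin, 1622 ± 76.4 with afatinib and 7739.6 ± 551 with both (interaction 1.87, SE 0.09, edgeR adjusted p = 3.99e-21). Neuronal genes under REST lay above the sum for 5 of 12 and below it for 0 (camera adjusted p = 0.00147), with adjusted p = 0.0505 with an estimated correlation. ATF4 targets lay below the sum for 14 of 25 and above it for 4, 15 and 4 adjusted over the list alone (camera adjusted p = 4.78e-05), with adjusted p = 0.098 with an estimated correlation. Within that list TRIB3 had an interaction of -1.86, SE 0.11, and ASNS one of 1.49, SE 0.28. S phase genes lay below the sum for 19 of 38 and above it for 3, 21 and 3 adjusted over the list alone (camera adjusted p = 0.000702), with adjusted p = 0.098 with an estimated correlation and DTL at -1.13, SE 0.12. Homologous recombination genes lay below it for 12 of 28 and above it for 1 (camera adjusted p = 0.00511), with adjusted p = 0.0555 with an estimated correlation, NBN at -1.11, SE 0.12 and BRCA2 at -1.01, SE 0.15.

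The drug targets and the cell death genes moved gene by gene rather than as lists. Only 5 of 16 members of the ERBB list were abundant enough to be tested, and its lowest camera adjusted p over the 6 comparisons was 0.364. EGFR had 20 counts over the 3 DMSO libraries, 17 with romidepsin, 21 with afatinib and 9 with both, ERBB3 had 9, 11, 18 and 34, and ERBB4 had at most 3 counts in any library. ERBB2 (chromosome 17, 39687914 to 39730426) was at 4.99 ± 1.27 CPM in DMSO, 5.57 ± 1.35 with romidepsin, 11.1 ± 0.783 with afatinib (log2 fold change 1.16, SE 0.19, edgeR adjusted p = 9.93e-07) and 8.72 ± 1.15 with both (log2 fold change 0.81, SE 0.19, edgeR adjusted p = 0.000175). The last call was lost without the libraries holding keratin reads (0.56, edgeR adjusted p = 0.0726). Among 17 tested histone deacetylase genes (lowest camera adjusted p = 0.0862), 10 rose and 3 fell with romidepsin, 11 and 3 adjusted over the list alone. HDAC7 changed by -1.44 and HDAC11 by 0.96. HDAC1 fell with each treatment, by log2 fold changes of -0.36 with romidepsin, -0.42 with afatinib and -0.51 with both. HDAC3 had 0.63, -0.56 and 0.59 in the same order. HDAC2 had 0.31 with romidepsin, lost without romidepsin replicate 1 (0.23, edgeR adjusted p = 0.0634). Of 9 tested pro-death members of the BCL2 family (lowest camera adjusted p = 0.108), BCL2L11, which encodes BIM (chromosome 2, 111119378 to 111168445), rose from 2.04 ± 0.206 to 29.2 ± 3.08 CPM with romidepsin (log2 fold change 3.84, SE 0.16, edgeR adjusted p = 9.02e-26) and 30.6 ± 1.55 CPM with both (log2 fold change 3.90, SE 0.16, edgeR adjusted p = 1.1e-26). BMF rose by 2.98 and 3.00, and BAX fell by -1.18 and -1.43. Of 5 tested pro-survival members (lowest camera adjusted p = 0.624), BCL2L1, which encodes BCL-XL, changed by -1.84 with romidepsin and -1.96 with both, and MCL1 by 0.72 and 0.84. The death receptor gene FAS changed by -2.88 and -3.11 in a list of 23 tested death receptor and caspase genes (lowest camera adjusted p = 0.479). The p53 target TP53INP1 changed by 4.31 and 4.54 in a list of 22 (lowest camera adjusted p = 0.46).

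The JAK-STAT components, 26 tested, did not pass as a list in any of the 6 comparisons (lowest camera adjusted p = 0.0657), with members moving both ways. STAT3 went from 206 ± 9.97 to 807 ± 14.8 CPM with romidepsin (log2 fold change 1.97, SE 0.05, edgeR adjusted p = 1.75e-33) and 776 ± 6.57 CPM with both drugs. STAT5A fell by log2 fold changes of -1.33 with romidepsin, -0.38 with afatinib and -1.90 with both. STAT5B fell by -1.13 and -1.39 with romidepsin and with both, and JAK3 by -1.63, -0.34 and -1.86. JAK1 rose by 0.80 with romidepsin and 0.88 with both. MYC rose by 0.64 with romidepsin and 0.18 with both. Its value with afatinib (-0.31) lost its call without the libraries holding keratin reads (-0.18, edgeR adjusted p = 0.115). The 14 tested CDK inhibitors and G1 cyclins did not pass as a list (lowest camera adjusted p = 0.239), and neither did the 5 drug transporters (0.518), for which ABCB1 had at most 2 counts over the libraries of any group. Markers of other cell types were few. The 5 tested B cell markers (lowest camera adjusted p = 0.411) included CD22 (-2.60 with romidepsin, -2.34 with both). The 7 tested keratinocyte and fibroblast markers (lowest 0.186) included COL1A1, at 119 ± 14.3 CPM in DMSO, 14.7 ± 2.78 with romidepsin, 54.3 ± 0.462 with afatinib and 8.68 ± 0.345 with both. Lists with fewer than 5 tested members were not tested as lists. In the combination against DMSO, the 3 tested myeloid markers included CSF1R (1.05) and ITGAM (-2.43), the 4 tested cytotoxic granule genes included PRF1 (-1.23), and the 2 tested metallothioneins included MT2A (-0.83), which shares reads with its copies and is uncertain.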

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

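For the interferon-stimulated genes, the tests of low DMSO levels and of a ceiling were chosen after the result was seen, while those of scaling and of single libraries, and the other splits of the samples, were written down before they were run. Each result here stands out because the effect of a drug alone differed from its effect in the presence of the other drug by edgeR's or camera's test of the interaction.

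The interferon-stimulated genes had a median log2 fold change of 1.31 with afatinib alone (camera adjusted p = 0.000265) and of -0.46 with afatinib on top of romidepsin, which did not pass (camera adjusted p = 0.0657), with a median interaction of -1.14 (camera adjusted p = 6.19e-10). Seen from the other drug, with the same median interaction of -1.14, the list had a median of 0.52 with romidepsin alone, which did not pass (camera adjusted p = 0.231), and of -0.73 on top of afatinib (camera adjusted p = 0.0237, lost at 0.0704 with an estimated correlation). Endoplasmic reticulum chaperone and unfolded protein response genes had a median interaction of 0.314 (camera adjusted p = 0.000301), with afatinib at -0.24 alone (camera adjusted p = 0.157) and 0.13 on top of romidepsin (camera adjusted p = 0.118). Costimulatory and inhibitory receptors had a median interaction of -0.534 (camera adjusted p = 1.08e-06), with afatinib at 0.03 alone (camera adjusted p = 0.724) and -0.51 on top of romidepsin (camera adjusted p = 0.00195).

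With both changes at least 2-fold, 7 genes were up with afatinib alone and down with afatinib on top of romidepsin, and 8 genes were down alone and up on top of it. HLF is the most abundant example of the first kind in the romidepsin libraries (99.6 ± 8.36 CPM there and 16.03 ± 1.73 in the combination), and NCKAP5L, with 23.7 ± 3.302 CPM in DMSO, 11.1 ± 1.303 with afatinib, 113 ± 5.07 with romidepsin and 302 ± 7.38 with both, of the second. For romidepsin, 8 genes were up alone and down on top of afatinib, such as ABCA13 (9.21 ± 2.25 CPM with romidepsin, 35.8 ± 3.59 with afatinib, 10.6 ± 1.72 with both), and 4 genes were down alone and up on top of afatinib, such as GPBAR1 (1.76 ± 0.857 CPM in DMSO, 0.634 ± 0.267 with romidepsin, 0.532 ± 0.242 with afatinib, 1.17 ± 0.24 with both). These examples, except HLF and ABCA13, were chosen after their values were seen.

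The negative interaction of the interferon-stimulated genes was weighed against technical explanations. Low levels in DMSO would inflate the sum. Where romidepsin itself does not lower a gene, they would leave the combination no lower than afatinib alone. The list lay lower in the combination than with afatinib, by a median of -0.726 against -0.023 for other genes (camera adjusted p = 0.0237, and 0.0704 with an estimated correlation). That median also covers members that romidepsin alone lowered from high DMSO levels, such as MX2 (96.7 to 104 CPM in DMSO, 38.4 to 44.1 with romidepsin). By itself it therefore does not decide the question for members low in DMSO. ISG15, IFI35, IFIT1, IFIT2, IFIT3, IFIT5, OASL and IRF7 had at most 26.4 CPM in any DMSO library, and afatinib raised them. Romidepsin did not lower their means, and all 3 combination libraries lay below all 3 afatinib libraries. For these members the values argue against low DMSO levels as the cause. In RSAD2, IFI6, IFI44, IRF9, DDX58 and USP18 the combination and afatinib libraries overlapped. The median interaction closest to zero was -1.072 over 3 other scalings and -1.112 with 1 library left out, so neither the scaling nor a single library accounts for it. A ceiling that either drug reaches would leave the combination at the level of the higher single drug, but its median log2 ratio to that drug was -0.87, and 9 of 23 members were called lower in the combination than with each single drug (edgeR, adjusted p below 0.05). The 23 members include some that each drug alone lowered, such as MX2 and OAS2, to which a ceiling does not apply. By themselves these values therefore do not decide the question for the members that the drugs raised. In ISG20, IFIH1 and the members from ISG15 to IRF7 named above, all combination libraries lay below all afatinib libraries. That argues against a ceiling for those members. The members whose libraries overlapped are not covered, and STAT2, which romidepsin raised, was higher in the combination than with either drug. A hypothesis that stays open is that both drugs together may hold back interferon signalling that afatinib alone can start, which measuring secreted interferon after each treatment would test.

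Other splits of the samples were tested beside these results. For 100 splits of the 12 libraries, 2 gave at least the 4898 interaction genes, the real one included, a share under 0.05. Most other splits mixed the treatments and called no genes, so this shows that the drugs changed genes and not that their effects depart from the sum. The highest other split gave 5712 and kept the 3 combination libraries together as 1 arm, which reflects the structure of the samples. For the 9 interaction lists, 55 of 100 splits gave as many (highest other 18), so that test does not exclude chance for the number of lists. For the 3562 genes that both drugs moved the same way, 2 of 100 splits gave as many, the real one included, a share under 0.05. Most other splits shared no calls at all, so this shows that the drugs changed genes and not that their responses are alike. The highest other split gave 6800 with the 3 romidepsin libraries in place of DMSO, which again reflects the structure of the samples. In each of the 5 pairwise comparisons the 10 splits of 6 libraries are too few for a share under 0.05. Only 1 of 10, the real one, gave as many genes, with 10139 called for romidepsin, 7351 for afatinib, 12036 for the combination, 8809 for the combination against romidepsin and 11219 against afatinib, and the highest other split gave 0. The lists in the same order were 13, 20, 16, 17 and 14, with the highest other splits at 10, 12, 12, 12 and 10.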

How the results depend on the processing

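All tests here were planned except those without the libraries holding keratin reads and without DMSO replicate 3 and romidepsin replicate 2 together, which were chosen after the result was seen. Of 952 named gene results, none that was past the threshold in the main fit or in an alternative changed direction under that alternative. In all, 22112 values stayed on their side of the threshold, 553 were no longer past it and 29 newly passed it. Values past the threshold in neither fit could change sign and still count among the 22112. Of the 553, 325 were lost to the 2-fold minimum by definition. Of the counts of genes and lists under the alternatives, 396 stayed within 1.5 times the reported count and 21 did not. Requiring a 2-fold change left 2157 higher and 1763 lower genes for romidepsin, 1031 and 412 for afatinib, 3424 and 2974 for the combination, 1293 and 778 for the combination against romidepsin, 2638 and 2568 against afatinib, 450 and 534 for the interaction, and 442 genes moved the same way by both drugs. This follows from the added minimum. With an estimated correlation, 8 lists passed for romidepsin, 11 for afatinib, 9 for the combination, 9 against afatinib and 3 for the interaction. Every list that passed with the estimated correlation also passed under each of the other alternatives run for lists. Without the libraries holding keratin reads, which keeps 1 DMSO library whose spread is assumed to be that of the other groups, 2164 genes were higher and 1998 lower with afatinib, and 1982 moved the same way with both drugs. This fit has fewer samples. In that fit the afatinib calls of the S phase list (adjusted p = 0.202), the heat shock chaperones (0.123) and both MHC lists (0.432) did not hold, and neither did that of the MHC class I list for romidepsin (0.118). Among single genes, the interactions of STAT5A, PMAIP1, HDAC1 and ABCC5 and the change of BLK in the combination against romidepsin lost their calls under many alternatives. The cause was not tested. The replicate numbers do not pair the samples. Deviations from the group mean correlated with r between -0.09 and 0.089 for the same number (18 pairs, across genes), and 4 of 12 libraries correlated best with their own number. With the replicate block, 4995 and 5055 genes were called for romidepsin, 3513 and 3710 for afatinib, 5998 and 5970 for the combination, 4013 and 4685 against romidepsin, 5390 and 5758 against afatinib, 1849 and 2947 for the interaction and 3488 the same way by both drugs, and the hypoxia list for romidepsin was no longer past the threshold (adjusted p = 0.0507). Depth limits the rarest genes, since 3 counts correspond to 0.236 to 0.334 CPM, and simulated 1.5-fold changes were recovered for 60% of genes in the interaction.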

Other observations

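Of the tests here, those of a few abundant genes, of silent genes and both of a length trend shared by the DMSO libraries were chosen after the result was seen, and the others were written down before they were run. All patterns in this part were noticed in the data and are hypotheses.

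Among genes chosen as close to silent in DMSO, more reached 1 CPM in the combination than with either drug alone, for which background reads stay open below. A choice by low DMSO counts by itself favours higher values elsewhere, and the reverse count was not made. Only the difference between the treatments can therefore be read. Of 13084 genes with at most 3 counts over the DMSO libraries and a count elsewhere, 178 reached a mean of 1 CPM or more in the combination, 90 with romidepsin and 8 with afatinib, and 58 did so in both romidepsin and the combination. Examples chosen after their values were seen are SLCO2B1, an organic anion transporter gene at 11.6 CPM in the combination, 7.84 with afatinib and 0.843 with romidepsin, TMEM169 at 8.52 with both and 5.22 with romidepsin, CYP46A1, a cholesterol hydroxylase gene at 6.45 and 1.68, and DNER, the gene of a neuronal Notch ligand, at 4.73 and 2.09.

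The nuclear long non-coding RNAs NEAT1 and MALAT1, named after their values were seen, were higher with each treatment. NEAT1 went from 1105 ± 286 CPM in DMSO to 5507 ± 753 with romidepsin, 2817 ± 219.7 with afatinib and 6825 ± 140.2 with both (log2 fold change 2.63 for the combination, edgeR adjusted p = 7.67e-07), and MALAT1 from 326 ± 90.9 to 598 ± 92.9, 501 ± 17.3 and 826 ± 60.4 (1.34, edgeR adjusted p = 0.000141).

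More genes had a count in the romidepsin and combination libraries than in DMSO. Depth does not account for it, since after thinning every library to the lowest total the lowest combination library still had 1333 more such genes than the highest DMSO library (21757 ± 436 genes in DMSO, 22520 ± 124 in afatinib, 23004 ± 203 in romidepsin and 23647 ± 55.5 in the combination). A few abundant genes do not account for it either, since without the 14 genes that were among the 10 most abundant of any library the same difference after thinning was 1336 genes. Reads spread evenly over silent genes stay open as an explanation: coding olfactory receptor genes without a count in 1 DMSO library rose 2.696-fold in summed CPM (95% interval 1.48 to 5.40 from 2000 resamples of 376 genes), a range that holds the 3.85-fold of other silent coding genes. The gain may therefore come from genomic DNA or broad background transcription as well as from histone deacetylase inhibition, which the design names and no measurement here tests.

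The interaction was more negative in genes with a longer genomic span (Spearman correlation -0.181 across 11904 genes, which are not independent replicates), with a median of 0.004 up to 5 kb, 0.06 at 5 to 10 kb and -0.25 above 160 kb, so the trend did not hold across the shortest genes. A trend in a single DMSO library is argued against by -0.158, the value closest to zero with 1 DMSO library left out, and the abundance of the genes by -0.169, the value closest to zero over 3 classes of mean CPM. Long genes raised by both drugs that fall short of the sum are excluded as the whole cause by -0.226 among the 2332 genes whose single-drug changes sum to near zero. A length trend shared by the DMSO libraries would leave none against either drug, so it is argued against as the whole cause by the correlation of -0.063 between the combination and romidepsin (-0.085 to -0.046 with 1 library left out). As a part of the pattern it stays open, because the combination and afatinib had 0.022 (0.009 to 0.029 with 1 library left out), and romidepsin, afatinib and the combination had 0.135, 0.119 and 0.062 against DMSO.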
